A study of Mus musculus with 37 samples.

How the data were processed

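ATAC-seq measures open chromatin: the Tn5 transposase inserts sequencing adapters where DNA is accessible, and the read count of a region follows its accessibility. The samples are nuclei from the nucleus accumbens of adult mice that carry a Cre-dependent Sun1-GFP protein of the nuclear envelope and Cre under control of Pvalb (parvalbumin, PV) or Sst (somatostatin, SST). GFP-tagged nuclei were isolated with an anti-GFP antibody (IP), and the unbound fraction (UF) is the supernatant of that step. Per the labels, each library comes from 1 mouse, so libraries were treated as independent biological replicates. As UF is the supernatant of an IP, an IP and a UF library may share a mouse. The labels do not say so, and the main tests did not pair them. Sodium butyrate, an inhibitor of histone deacetylases, was present in the isolation buffers.

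The deposited values are raw counts of reads per 200 bp region on the mouse build mm10, in 3 tables: PV at 60 min (205,848 regions, 16 libraries), SST (178,637 regions, 6 libraries) and PV at 24 h (171,130 regions, 15 libraries). The submitters' processing notes name FastQC 0.11.2, cutadapt 1.8.3, Bowtie2 2.3.4.3, bedtools 2.25.0, MACS2 2.1.2, R 3.4.4, DESeq2 1.18.1 and deepTools. How the regions were merged or pooled over libraries is not stated, and no read shift for the Tn5 insertion is given in the sources used here. All values were checked to be whole numbers and all regions to be 200 bp wide, and every library column was matched to its sample. The regions were chosen on these libraries, so regions open in few libraries can be missing from a table, and the 3 tables hold different regions.

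Total counts per library ran from 0.651 to 15.1 M. No library is a copy of another: over the 51 pairs of libraries within a group, the chi-square per degree of freedom of the counts was 1.62 to 8.13. Precision is given as the standard error (SE) of each log2 fold change, which holds both counting error and the spread between libraries. The median SE over regions was 0.40 for PV IP against UF at 60 min, 0.30 for SST and 0.71 for PV at 24 h.

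Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10 and a minimum total count of 15, a robust quasi-likelihood fit, the two-sided quasi-likelihood F test and Benjamini-Hochberg adjustment. "Called" means an adjusted p under 0.05, and a log2 fold change is IP over UF or amphetamine (AMPH) over saline. Fits were made for IP against UF in saline libraries of each table, for AMPH against saline within each fraction and time, and for the interaction of AMPH with fraction. Fits of the 24 h table carry a term for the isolation number (Iso) of the title. All saline IP libraries of that table are Iso2. The fold of IP against UF at 24 h therefore rests on the Iso2 libraries (in UF, libraries Iso2-1 and Iso2-2). In AMPH against saline in IP, AMPH library Iso1-1 is the only Iso1 library, so that fold also rests on the Iso2 libraries. The CPM means beside these folds cover all libraries of a group. The other 24 h fits estimate the Iso term from groups that hold both numbers.

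For the gene level, counts were summed over the regions that overlap the body of a protein-coding gene or the 2 kb on either side (21,887 genes, RefSeq annotation of GRCm38.p6, the assembly of mm10), with GenomicRanges 1.54.1 in place of the planned bedtools. The annotation used has no strand, so both sides stand in for the planned 2 kb upstream. A region can count for more than 1 gene. CPM are counts scaled to equal library size after TMM, as edgeR defines them.

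Before the data were examined, 18 gene lists (224 entries, 215 genes) were fixed: PV interneuron, SST interneuron, regulators of interneurons from the medial ganglionic eminence (MGE), GABA synthesis and release, cholinergic interneuron, spiny projection neuron (SPN), cortical glutamatergic neuron, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial and mural, immediate early, late response, dopamine and cAMP signalling, perineuronal net, glutamate and GABA receptors, and housekeeping. The SPN list and the dopamine list share 8 genes, and the oligodendrocyte precursor and perineuronal net lists share 1. Lists were tested against the other genes with camera of limma 3.58.1 on log2 CPM (prior count 2). Camera was run with a preset correlation between genes of 0.01 and beside it with an estimated correlation. Fry was run on the same values and tests whether the genes of a list shift in one direction. It does not compare a list with the other genes, so a list can pass fry where many genes differ. The models, filters, lists and the rule for named regions were chosen before the data were examined.

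Named regions for IP against UF are the 10 with the highest and the 10 with the lowest log2 fold change among those called, with an edgeR logCPM of at least 2 and every IP library on one side of every UF library, at most 1 region per gene. For AMPH the logCPM limit is dropped, and where fewer than 5 regions in a direction pass, the rule names the 5 with the smallest p as not passing. Fewer of these are printed below, and at 24 h only called regions are. At the gene level the members of the lists are named, with Pvalb and Sst first.

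Overlap between tables is counted for called regions that share at least 1 bp, with Fisher's exact test over regions tested in both. Differences in the IP over UF fold change between tables were tested at the gene level in 1 edgeR fit. Each gene was summed over the regions of its own table, so the sums compared can cover different regions. Library totals and shares of counts were compared by two-sided exact permutation tests. Beside the totals, these tests covered the share of counts in stretches of chromosomes 1 and 2 that carry nuclear copies of mitochondrial DNA (mitochondrial-like share) and the share in the first 50 kb of assembled sequence of chromosome 9, from 3.0 Mb on near the centromere; the chromosome 9 share was chosen after the called regions were seen. The fraction score of a PV library is the mean log2 CPM of genes called higher in PV IP minus that of genes called lower, with the genes taken from the other PV table.

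What the fits can detect was tested on simulated data: negative binomial counts with the means, totals and dispersions of each comparison, in which 50 regions or genes at each of 4 folds differed between the groups. Alternatives tried were RLE size factors, scaling by totals alone, no filter, DESeq2 1.42.0, all libraries of a table in 1 fit, an adjusted p under 0.10, a minimum absolute log2 fold change of 1, the replicate number as a block, no Iso term, Iso2 libraries alone, and each library left out in turn. Alternatives added after the data were seen were regions within 1 kb of either gene end, leaving out the chromosome 9 stretch and mitochondrial-like regions, leaving out the 2 shallowest libraries or those of low fraction score, the fraction score as a covariate and a term for odd or even replicate numbers. Tests that need transcription start sites or genome sequence (regions within 1 kb of a start, the AP-1 motif) were not run, since neither was available.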

Results

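Chromatin accessibility was measured in nuclei of the nucleus accumbens, the ventral striatal region where amphetamine (AMPH) raises dopamine. PV+ nuclei and SST+ nuclei, from 2 classes of GABA interneurons that are rare among the spiny projection neurons (SPNs) and glia of this tissue, were pulled down (IP) and set beside the unbound fraction (UF). The 37 libraries fall into 10 groups. PV nuclei collected 60 min after a single injection of saline or 3 mg/kg AMPH gave 4 IP and 4 UF libraries per treatment. PV nuclei collected 24 h after the last of 6 daily injections gave 4 IP and 4 UF libraries after AMPH, 4 UF libraries after saline and 3 IP libraries after saline. SST nuclei gave 3 IP and 3 UF saline libraries.

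Total counts in regions ran from 5.22 to 9.57 M in the saline PV IP libraries at 60 min, 1.39 to 9.38 M in the AMPH ones, 5.67 to 14.7 M in saline UF and 4.24 to 15.1 M in AMPH UF. They ran from 6.57 to 9.40 M in SST IP and 9.38 to 11.8 M in SST UF. The 24 h libraries were shallower, with 0.651 to 5.50 M in saline IP, 2.59 to 9.66 M in AMPH IP, 0.769 to 3.52 M in saline UF and 2.2 to 6.00 M in AMPH UF. No pair of compared PV groups passed 0.05 for total counts in two-sided exact permutation tests, where the lowest p was 0.0857 (24 h UF, 4.67 ± 1.68 M after AMPH against 2.36 ± 1.33 M after saline, SD, n = 4 each). For SST (7.92 ± 1.42 M in IP against 10.9 ± 1.29 M in UF, n = 3 each) the exact permutation p was 0.2, and the smallest that 3 against 3 allow is 0.1.

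The targeted genes were more accessible in the fraction that was pulled down. Pvalb, which encodes the calcium-binding protein parvalbumin, had 78.4 ± 22.3 CPM in saline PV IP and 9.20 ± 1.34 CPM in UF at 60 min (SD, n = 4 each), and 53.5 ± 10.7 CPM (n = 3) against 7.95 ± 2.36 CPM (n = 4) at 24 h. Every PV IP library, at 42.3 CPM or more, lay above every UF library, at 10.9 CPM or less. Sst, which encodes the neuropeptide somatostatin, had 16.3 ± 3.41 CPM in SST IP against 1.51 ± 0.410 CPM in UF (SD, n = 3 each). In SST IP Pvalb had 10.2 ± 3.25 CPM against 7.47 ± 0.572 CPM in UF, a difference that did not pass the test (log2 fold change 0.45 ± 0.22 SE, adjusted p = 0.084). Sst had 4.32 ± 2.17 CPM in saline PV IP and 1.98 ± 0.447 CPM in UF at 60 min (log2 fold change 1.11 ± 0.40, adjusted p = 0.056). The single region tested in Sst was, however, called higher in PV IP (1.13 ± 0.40, adjusted p = 0.0288). At 24 h Sst had 0.914 ± 0.810 CPM in saline PV IP (n = 3) and 3.73 ± 4.11 CPM in UF (n = 4). UF library Iso2-2, on which the 24 h folds rest in part, had 9.83 CPM, against 1.19 to 2.55 CPM in the other UF libraries.

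**Figure D1:**
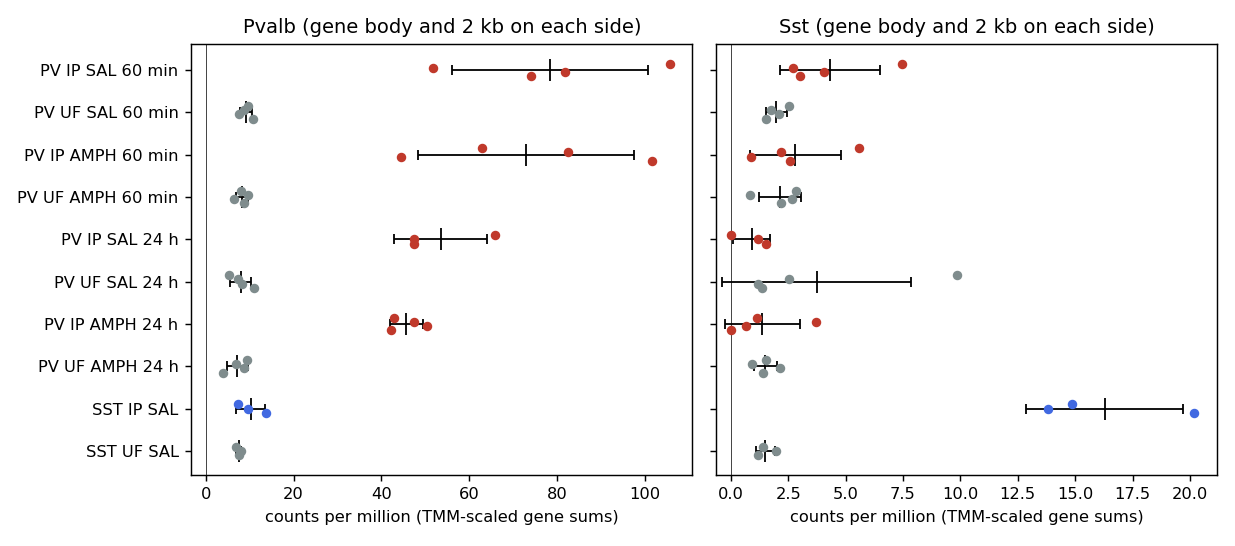
Accessibility of Pvalb and Sst (CPM) in each of the 37 libraries (points; red PV IP, blue SST IP, grey UF), with the mean and SD of each of the 10 groups (bars). Saline PV IP at 60 min averaged 78.4 CPM for Pvalb against 9.20 CPM in UF, and SST IP averaged 16.3 CPM for Sst against 1.51 CPM in UF.

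Within Pvalb (mm10 chromosome 15, 78,191,112 to 78,206,400), all 5 tested regions were called higher in PV IP at 60 min. The most strongly called lies at 78,195,637 to 78,195,836, with 25.0 ± 6.06 CPM in IP and 1.56 ± 0.83 CPM in UF (SD, n = 4 each; log2 fold change 4.06 ± 0.35, adjusted p = 4.8e-06). At 24 h the region at 78,195,601 to 78,195,800 had 22.2 ± 5.60 CPM in IP (n = 3) and 0.588 ± 0.699 CPM in UF (n = 4); of the 3 regions tested there 2 were called and 1 did not pass (1.91 ± 0.73, adjusted p = 0.0538). In SST IP the region at 78,195,605 to 78,195,804 differed from UF by 0.61 ± 0.38 (adjusted p = 0.19). The single tested region in Sst in the SST table (chromosome 16, 23,890,861 to 23,891,060) had 12.7 ± 3.14 CPM in SST IP and 1.32 ± 0.339 CPM in UF (n = 3 each; log2 fold change 3.28 ± 0.26, adjusted p = 4.1e-18).

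**Figure D2:**
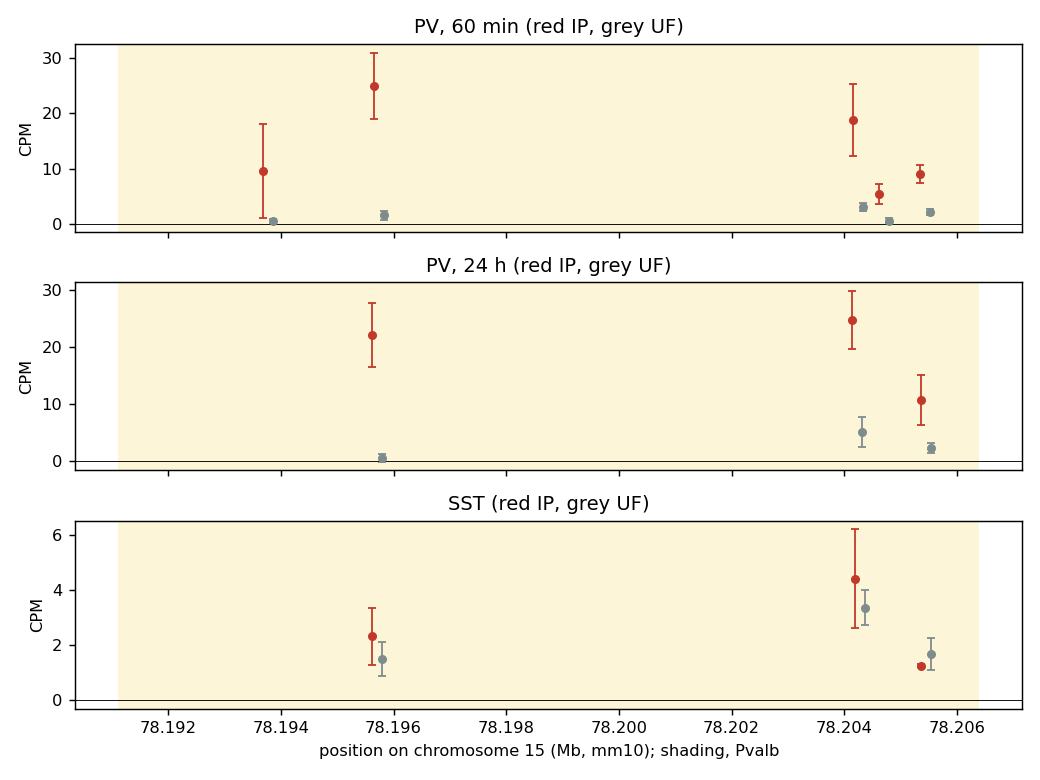
Mean and SD of the CPM of each tested region in Pvalb along chromosome 15 (shaded: the gene), for IP (red) and UF (grey) in PV at 60 min, SST and PV at 24 h; the y scales differ between panels. The region near 78.2 Mb with the highest IP mean at 60 min had 25.0 CPM in PV IP and 1.56 CPM in UF.

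The comparison of PV IP with UF in saline mice at 60 min asks which chromatin is open in PV+ nuclei relative to the unbound nuclei of the same tissue. Called genes of PV interneurons (11 of 13) and of their lineage from the medial ganglionic eminence (MGE, 9 of 12) were more accessible in PV IP, and called genes of oligodendrocytes (12 of 12) and SPNs (13 of 22) were less accessible; no list held as a set with an estimated correlation. Kcns3, a potassium channel subunit of fast-spiking cells, had 38.5 ± 9.93 CPM in IP and 7.74 ± 1.51 CPM in UF (SD, n = 4 each; log2 fold change 2.31 ± 0.23 SE, adjusted p = 2.5e-05). Olig2, a transcription factor of the oligodendrocyte lineage, had 2.21 ± 0.363 CPM in IP and 19.2 ± 3.79 CPM in UF (log2 fold change -3.09 ± 0.26, adjusted p = 1.1e-05). Drd2, the dopamine D2 receptor of indirect-pathway SPNs, had 19.1 ± 3.98 CPM in IP and 53.6 ± 2.60 CPM in UF (log2 fold change -1.50 ± 0.17, adjusted p = 4.6e-05).

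Of the 13 PV interneuron genes, 11 rose in PV IP and none fell (11 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 1.22. Beside Pvalb and Kcns3 these included Vwc2 (1.57 ± 0.15), Cntnap4 (1.46 ± 0.18) and Syt2, the synaptotagmin of fast-spiking terminals (1.01 ± 0.10), whereas Kcnc1 (-0.03 ± 0.13) and Eya1 (-0.37 ± 0.17) did not pass the test. Of the 12 MGE genes, 9 rose and none fell (10 adjusted over the list alone), among them Lhx6, the transcription factor that specifies these interneurons (1.90 ± 0.27), Sox6 (1.13 ± 0.15) and Nkx2-1 (1.05 ± 0.29). The SST interneuron list was mixed: Cort (2.22 ± 0.34), Crhbp (1.70 ± 0.31) and Crhr1 (0.43 ± 0.14, but -0.48 and not called from regions at gene ends alone) rose, Nos1 fell (-0.93 ± 0.18), and the median was 0.31 (adjusted over the list alone, 4 higher and 2 lower). Of the 8 perineuronal net genes, whose products form the matrix around PV cells, 5 rose and 1 fell, also when adjusted over the list alone. Acan, its core proteoglycan aggrecan, rose by 1.90 ± 0.18, and Vcan fell (-0.51 ± 0.15).

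Markers of other cells differed by type. All 12 oligodendrocyte genes were lower in PV IP (12 adjusted over the list alone; median -1.87), with Mag at -2.75 ± 0.32. Of 22 SPN genes, 13 fell and none rose (15 adjusted over the list alone; median -0.61), including Rgs9 (-1.19 ± 0.11), Ppp1r1b (-1.04 ± 0.17) and Penk (-0.96 ± 0.19), while Drd1 (-0.35 ± 0.34) did not pass. Of 16 genes of dopamine and cAMP signalling, 8 of which are SPN genes, 9 fell (10 adjusted over the list alone). Of 9 microglia genes, 4 fell, with Cx3cr1 at -2.67 ± 0.33; of 6 oligodendrocyte precursor genes 4 fell and 1 rose; and 2 of 11 astrocyte genes and 2 of 10 cortical glutamatergic genes fell (the same counts adjusted over each list alone). The endothelial and mural list went the other way: 5 of 10 genes rose and none fell (6 adjusted over the list alone; median 0.85), including the transporter Slco1a4 at 10.6 ± 12.5 CPM against 0.968 ± 0.228 CPM (3.43 ± 0.68) and Tek, a receptor of endothelial cells (2.03 ± 0.27). Of 6 cholinergic genes 2 rose, Lhx8 (1.47 ± 0.32) and Ecel1 (1.12 ± 0.22), and Chat did not pass (-0.21 ± 0.28). The mitochondrial-like share was 2.06 ± 1.33% in IP and 0.724 ± 0.381% in UF (SD, n = 4 each, exact permutation p = 0.0857).

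Camera with the preset correlation of 0.01 placed 10 of the 18 lists past an adjusted p of 0.05, higher for PV interneuron (9.7e-08), MGE (4.1e-06), perineuronal net (0.00527), endothelial and mural (0.00527) and cholinergic (0.0425), and lower for oligodendrocyte (4.4e-09), SPN (1.5e-07), dopamine (5.3e-05), microglia (0.00555) and cortical glutamatergic (0.0425). None held with an estimated correlation: adjusted p = 0.0896 with an estimated correlation for the PV, MGE, oligodendrocyte, SPN and dopamine lists, 0.141 for endothelial and mural, 0.153 for cholinergic, 0.228 for perineuronal net, 0.279 for microglia and 0.289 for cortical glutamatergic. Fry passed all 10 of these lists (adjusted p = 0.0202 or less). Beyond these it passed the oligodendrocyte precursor (8.6e-04), SST interneuron (0.0486) and late response (0.0486) lists.

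**Figure D3:**
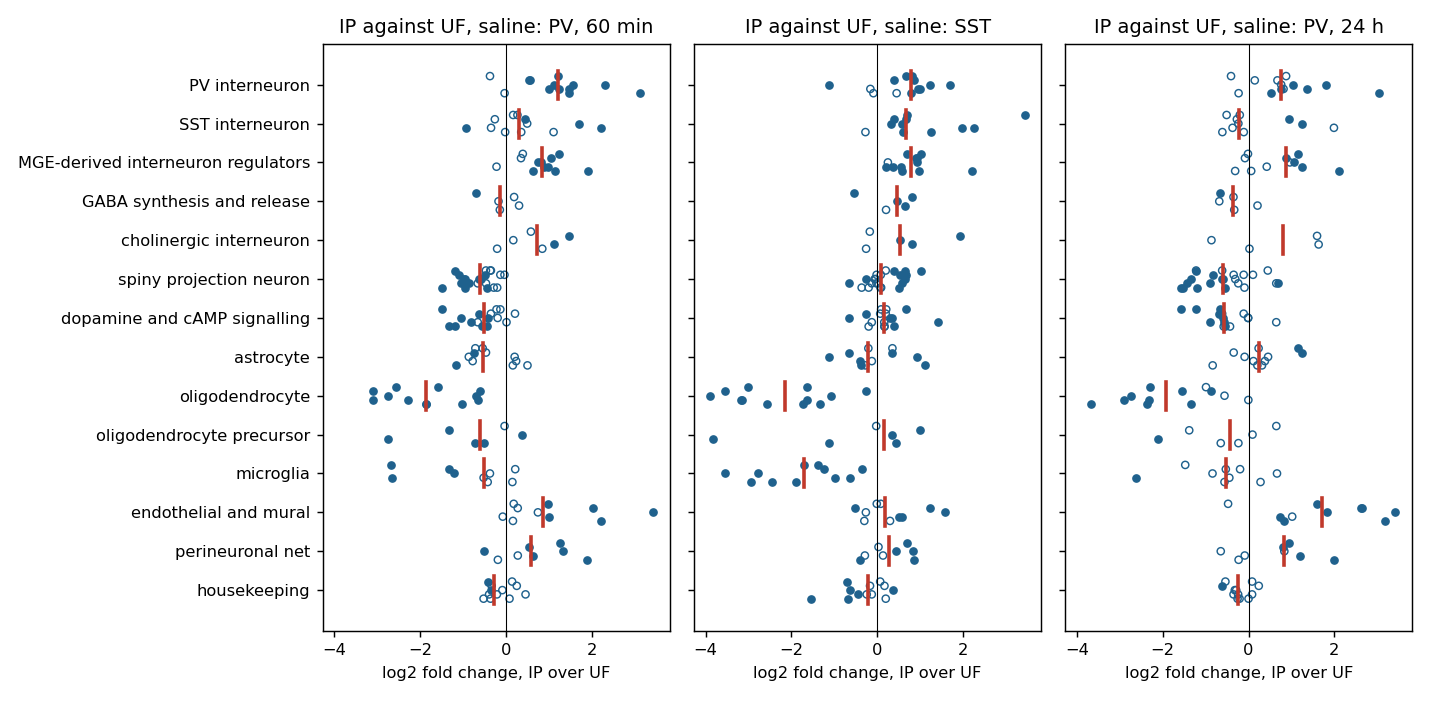
Log2 fold change of IP over UF for each gene of 14 lists (points; filled, adjusted p under 0.05; open, not) in PV at 60 min, SST and PV at 24 h, with the list median (red line, lists of 3 or more tested genes). The median of the oligodendrocyte list was -1.87, -2.15 and -1.92 in the 3 panels, and that of the SPN list -0.61, 0.08 and -0.60.

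By region, edgeR called 39,267 regions higher and 42,572 lower in PV IP, of 182,547 tested, and by gene 2000 higher and 2232 lower of 16,957. This fit did not pair IP and UF libraries, and with the replicate number as a block more regions and genes were called. Of the 10 named higher regions 8 lay outside genes. The highest, at 95,667,579 to 95,667,778 on chromosome 2 with Lrrc4c as the nearest gene, had 8.61 ± 8.60 CPM in IP and 0.128 ± 0.213 CPM in UF (log2 fold change 5.99 ± 0.87, adjusted p = 9.0e-05). A region in Hdac9, a histone deacetylase gene (chromosome 12, 34,185,636 to 34,185,835), had 10.6 ± 10.3 CPM in IP and 0.274 ± 0.128 CPM in UF, and one in the olfactory receptor gene Olfr287 (chromosome 15, 98,212,447 to 98,212,646) had 18.4 ± 8.97 CPM and 0.519 ± 0.273 CPM (SD, n = 4 each). Of the 10 named lower regions, at log2 fold changes of -4.40 to -3.94, 9 lay outside genes, and the other lay in Tmem125 (chromosome 4, 118,542,595 to 118,542,794; -4.04 ± 0.54, adjusted p = 3.2e-05). Counts of regions within 1 kb of either gene end alone gave 2226 called genes, and Pde10a, called lower over whole genes (-0.63), was higher at the gene ends (0.76).

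The comparison of SST IP with UF asks the same of SST+ nuclei. Called genes of SST interneurons (10 of 11) and of the MGE lineage (11 of 12) were more accessible in SST IP, and called genes of oligodendrocytes (12 of 12) and microglia (11 of 11) were less accessible; no list held as a set with an estimated correlation. Sst rose by 3.45 ± 0.25 (adjusted p = 9.3e-09) and Npy, which encodes neuropeptide Y, had 13.2 ± 1.60 CPM in IP against 2.81 ± 0.471 CPM in UF (SD, n = 3 each; adjusted p = 2.1e-07). Mag, a myelin protein gene, had 2.32 ± 0.582 CPM in IP against 35.2 ± 0.713 CPM in UF (log2 fold change -3.90 ± 0.19, adjusted p = 1.8e-10).

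Of 11 SST interneuron genes, 10 rose and none fell (median 0.68), with Crhbp at 1.96 ± 0.15 and Chodl, a marker of long-range SST cells, at 1.24 ± 0.13. Nos1 did not pass (-0.28 ± 0.14). Of 12 MGE genes 11 rose (12 adjusted over the list alone; median 0.79), with Lhx6 at 2.22 ± 0.16. Of 13 PV interneuron genes 9 rose and Cox6a2 fell (-1.12 ± 0.23; median 0.79); the highest was Kcns3 (1.69 ± 0.12). Of 5 GABA genes 3 rose, among them Slc32a1, the vesicular GABA transporter (0.81 ± 0.11), and 1 fell (4 and 1 adjusted over the list alone). All 12 oligodendrocyte genes and all 11 microglia genes fell, with medians of -2.15 and -1.71, as did 6 of 10 cortical glutamatergic genes (8 adjusted over the list alone). SPN genes were mixed, with 8 higher and 2 lower of 22 (median 0.08): Pdyn (1.02 ± 0.21) and Rgs9 (0.39 ± 0.09) rose, Ppp1r1b fell (-0.65 ± 0.12), and Drd2 did not pass (0.09 ± 0.15). Of the dopamine genes 5 rose and 2 fell of 16, and of the endothelial and mural genes 4 rose, among them Tek (1.23 ± 0.20), and Kdr fell (-0.53 ± 0.13). The astrocyte list had 3 genes higher and 4 lower of 11, the oligodendrocyte precursor list 3 higher and 2 lower of 6 (median 0.16, mean -0.54 and camera downward), the perineuronal net list 4 higher and 1 lower of 8, and the cholinergic list 3 higher and none lower of 5. Where not given, counts adjusted over the list alone were equal. The mitochondrial-like share was 0.871 ± 0.0658% in IP and 0.377 ± 0.0839% in UF (SD, exact permutation p = 0.1, the smallest that 3 against 3 libraries allow).

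With the preset correlation, camera called the oligodendrocyte (adjusted p = 4.9e-08), microglia (3.6e-05) and cortical glutamatergic (0.0245) lists lower and the MGE (8.7e-05), SST (1.6e-04) and PV (0.00238) lists higher. None held with an estimated correlation: adjusted p = 0.0595, 0.361, 0.187, 0.0733, 0.0733 and 0.113 with an estimated correlation, in the same order. Fry passed all of these lists (adjusted p = 0.00208 or less), and also the housekeeping list (2.1e-04). Only the astrocyte (0.246), immediate early (0.0717) and late response (0.362) lists did not pass fry. As 58.3% of genes were called, fry hardly tells lists apart here and does not single out those that camera called. edgeR called 42,819 regions higher and 40,412 lower of 177,788, and 4877 genes higher and 4960 lower of 16,883. Among the named regions, one in Pard3b (chromosome 1, 61,793,747 to 61,793,946) had 8.29 ± 2.00 CPM in IP and 0.128 ± 0.0712 CPM in UF, and one outside genes on chromosome 8 (103,144,419 to 103,144,618, nearest gene Cdh11) had 30.8 ± 6.02 CPM and 0.664 ± 0.238 CPM (log2 fold change 5.49 ± 0.25, adjusted p = 1.7e-29). The 10 named lower regions, at -5.40 to -5.08, included regions within 2 kb of Mag (chromosome 7, 30,916,845 to 30,917,044; -5.23 ± 0.41) and of Ppp1r14a (-5.16 ± 0.38) and one in Plekhh1 (-5.30 ± 0.35). At gene ends alone Pde10a (0.48) and Mbp (0.78), both called lower over whole genes, were higher in SST IP.

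The regions of the PV and SST tables overlapped beyond chance. Among 124,839 regions tested in both, 11,503 of the 19,602 called higher in PV IP were also called higher in SST IP (58.7%, against 4078 by chance, odds ratio 8.91), and 13,645 of the 33,161 called lower were also called lower (41.1%, against 8077 by chance, odds ratio 3.13). Opposite calls numbered 695 and 2471. The PV and SST tables were then compared gene by gene. The IP over UF fold change differed for 3653 of 16,578 genes, 1866 higher in PV and 1787 higher in SST. PV exceeded SST at Pvalb (2.67 ± 0.33, adjusted p = 3.3e-05), Cox6a2 (2.26 ± 0.37), Syt2 (1.01 in PV and -0.16 in SST) and Btbd11 (0.67 ± 0.19), and SST exceeded PV at Sst (-2.33 ± 0.50, adjusted p = 0.00282). SPN genes were lower in PV, 12 of 22 and none higher (median difference -0.86, adjusted p = 0.00754 with an estimated correlation), with Drd2 at -1.59 ± 0.24, Rgs9 at -1.58 ± 0.15 and Penk at -1.03 ± 0.24, as were 8 of 16 dopamine genes (median -0.63, adjusted p = 0.0207 with an estimated correlation). The PV interneuron list (median 0.47; adjusted p = 0.0422 preset and 0.469 with an estimated correlation), the SST interneuron list (median -0.53; 0.00374 and 0.0511) and the endothelial and mural list (median 0.81; 0.119 and 0.469) did not pass with an estimated correlation. The PV and SST libraries are separate sets, so the Cre line and the table cannot be told apart. Each gene was also summed over different regions in each table, chosen on that table's own libraries. Part of a difference can come from the regions. The count was 2263 genes without SST IP library 3, 2317 without SST IP library 2 and 2377 without SST UF library 3.

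PV IP and UF were also compared in saline mice of the 24 h experiment, after 6 days of injections. With the Iso term, these folds rest on the IP libraries and on UF libraries Iso2-1 and Iso2-2, while the CPM means cover all UF libraries. Called genes of the PV and MGE lists were again more accessible in PV IP (6 of 13 and 5 of 11), called oligodendrocyte genes less (9 of 12) and called endothelial and mural genes more (8 of 10), while of 22 SPN genes 11 fell and 1 rose. Pvalb rose by 3.03 ± 0.36 (adjusted p = 3.4e-08) and Cldn5, a tight junction gene of brain endothelium, by 3.18 ± 0.39 (46.3 ± 15.1 CPM, n = 3, against 3.87 ± 1.52 CPM, n = 4; adjusted p = 5.9e-08). Lhx6 had 39.6 ± 10.1 CPM in IP and 10.2 ± 1.43 CPM in UF (adjusted p = 2.6e-05). Mag fell (-2.75 ± 0.49, adjusted p = 5.6e-05), and so did Drd2 (-1.57 ± 0.29, adjusted p = 1.1e-04).

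Of 13 PV interneuron genes 6 rose and none fell (7 adjusted over the list alone; median 0.76), and of 11 MGE genes 5 rose (6 adjusted over the list alone; median 0.87). Of 10 SST interneuron genes Crhbp (1.26 ± 0.44) and Satb1 (0.95 ± 0.30) rose (median -0.22, mean 0.19). The endothelial and mural list had 8 of 10 genes higher (median 1.71; 9 higher and 1 lower adjusted over the list alone), with Tek at 2.64 ± 0.35 and Kdr at 2.62 ± 0.44. Of 12 oligodendrocyte genes 9 fell (10 adjusted over the list alone; median -1.92). Of 22 SPN genes 11 fell and Ebf1 rose (0.69 ± 0.22; adjusted over the list alone 13 and 1; median -0.60), and of 15 dopamine genes 8 fell (9 adjusted over the list alone). The perineuronal net list had 4 of 8 genes higher (adjusted over the list alone 5 higher and 1 lower), with Acan at 2.00 ± 0.35. Of the 11 astrocyte genes 2 rose, of the 9 microglia genes 1 fell and of the 6 oligodendrocyte precursor genes 1 fell, and none of the 8 cortical glutamatergic and 4 cholinergic genes was called (adjusted over the list alone, 2 cholinergic genes rose and 1 fell). The mitochondrial-like share was 1.20 ± 0.712% in IP and 0.533 ± 0.197% in UF (SD, n = 3 and 4, exact permutation p = 0.0857).

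Camera with the preset correlation called the oligodendrocyte (adjusted p = 3.4e-09), SPN (3.4e-04) and dopamine (4.3e-04) lists lower and the endothelial and mural (6.6e-07), PV (3.4e-04) and MGE (0.00249) lists higher. None held, with adjusted p = 0.154 for oligodendrocyte and 0.249 for the others with an estimated correlation. Fry passed all of these lists (adjusted p = 0.0169 or less). Beyond these it passed the GABA, microglia and late response lists (0.0086 each) and the perineuronal net list (0.0256). edgeR called 7388 regions higher and 7347 lower of 77,164, and 1145 genes higher and 1245 lower of 16,056. The 10 named higher regions had no counts in the Iso2 UF libraries, so their folds are not given; the one in Flt1, a VEGF receptor (chromosome 5, 147,657,933 to 147,658,132), had 28.3 ± 4.71 CPM in IP (n = 3) against 0 CPM in UF (n = 4). The lowest named region (-5.75 ± 1.08) lay on chromosome 16 at 91,280,597 to 91,280,796, 8657 bp from Olig1. All 3 saline IP libraries are Iso2. DESeq2 called 9185 regions, and the count was 5812 regions and 1297 genes without IP library Iso2-2 and 8207 regions and 1369 genes without IP library Iso2-1. More regions were called with all libraries of the 24 h experiment in 1 fit, and with Iso2 libraries alone. Gene ends alone gave 1169 genes, with Pde10a, called lower over whole genes, at 0.83.

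Regions called at 60 min and at 24 h overlapped: 4184 higher (1107 by chance, odds ratio 13.8) and 6590 lower (1785 by chance, odds ratio 52.8), with 3 and 27 opposite. By gene, the IP over UF fold change differed between the experiments for 78 of 16,711 genes, 36 higher and 42 lower at 60 min (p under 0.05 unadjusted, 2757), and Pvalb differed by 0.17 ± 0.40 (adjusted p = 0.869). That count depends on single saline libraries. Among those of 60 min it was 37, 709 and 27 without IP library 1, 4 or 5 and 38, 20, 20 and 19 without UF library 1, 2, 4 or 5. Among those of 24 h it was 4 and 22 without IP library Iso2-2 or Iso2-3, and 31, 31, 2 and 453 without UF library Iso1-1, Iso1-2, Iso2-1 or Iso2-2. DESeq2 called 326.

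AMPH was compared with saline 60 min after injection to ask whether a single dose changes accessibility in PV+ nuclei or in the unbound nuclei. No gene passed in either fraction, and the immediate early genes, which neurons induce within minutes of activity, did not shift. Fos differed by -0.10 ± 0.21 in PV IP and by -0.03 ± 0.12 in UF (log2 fold change ± SE, n = 4 against 4). The 25 immediate early genes had a median of -0.05 in IP (range -0.55 to 0.36) and -0.07 in UF (range -0.27 to 0.09), and none reached an unadjusted p under 0.05 in edgeR. Pvalb was 72.9 ± 24.6 CPM after AMPH and 78.4 ± 22.3 CPM after saline in IP (SD, n = 4 each).

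**Figure D4:**
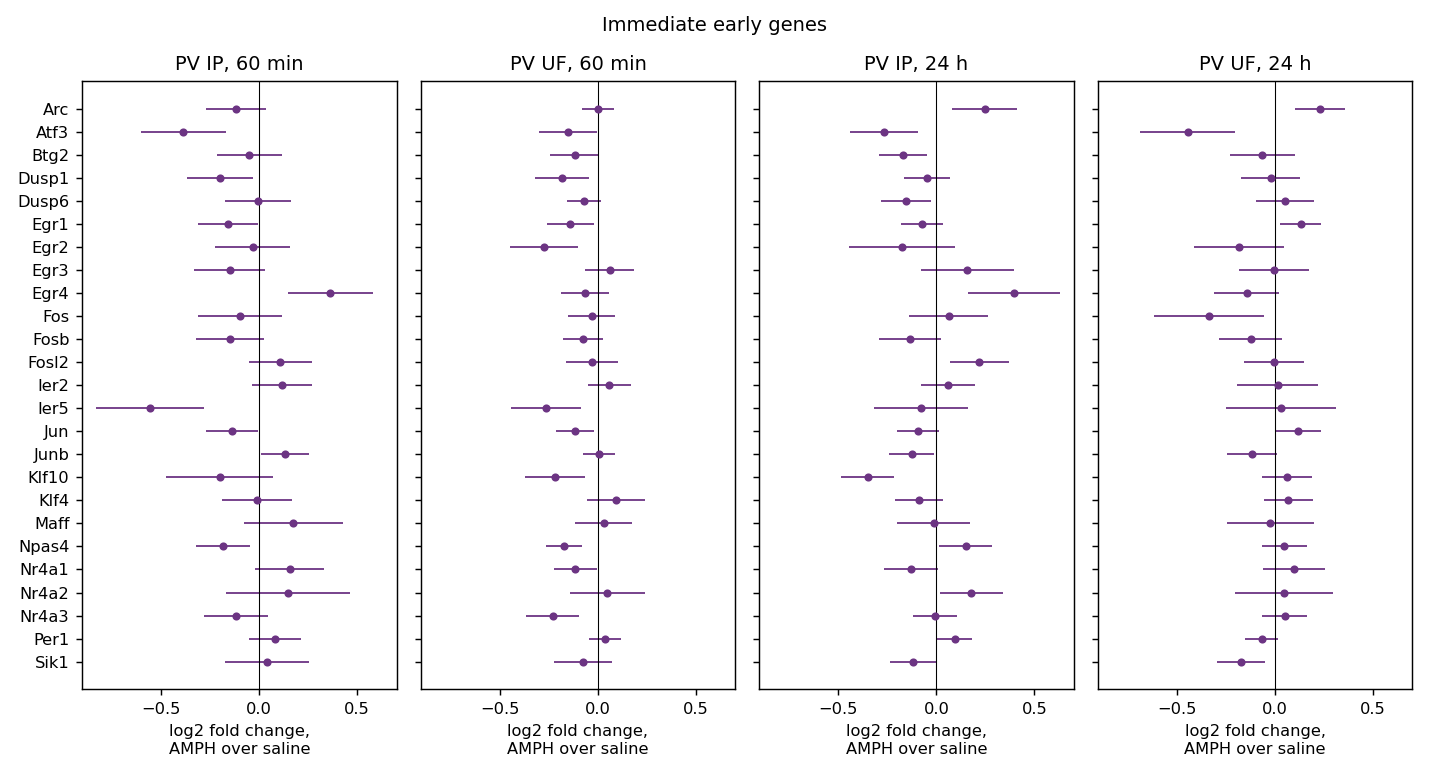
Log2 fold change of AMPH over saline (points, with SE as bars) for the 25 immediate early genes in PV IP and UF at 60 min and 24 h. At 60 min the values ran from -0.55 to 0.36 in IP and from -0.27 to 0.09 in UF, and none was called.

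No member of any list was called in either fraction at 60 min. The late response list had medians of 0.03 in IP and 0.05 in UF, and the dopamine list 0.13 and 0.08. Camera called the dopamine list higher in IP with the preset correlation (adjusted p = 0.0178), which did not hold (adjusted p = 0.877 with an estimated correlation). The SPN, oligodendrocyte and astrocyte medians in IP were 0.09, 0.22 and 0.10. Adjusted over the list alone, Gad2 was called higher in UF (0.27 ± 0.09), and no other gene of any list in either fraction. The mitochondrial-like share did not differ (IP exact permutation p = 0.971, UF 0.714).

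edgeR called 0 of 145,103 regions in IP (3434 at an unadjusted p under 0.05, or 2.37%; DESeq2 0) and 0 of 16,569 genes (257; DESeq2 0). In UF it called 0 of 170,436 regions (6476, or 3.80%; DESeq2 2) and 0 of 16,892 genes (606; DESeq2 0). The interaction of AMPH with fraction gave 0 of 198,998 regions (4139, or 2.08%; DESeq2 0). As no region passed, the 2 of smallest p in each direction are named as not passing. In IP these lay in Ralgapa2 (2.06 ± 0.42), Stap1 (2.82 ± 0.63) and Fig4 (-1.87 ± 0.46) and on chromosome Y at 90,765,519 (-0.90 ± 0.19). In UF they lay in Pde4d, a cAMP phosphodiesterase (1.95 ± 0.32), Spidr (2.29 ± 0.39) and Chchd5 (-0.96 ± 0.23) and on chromosome Y at 90,793,379 (-0.88 ± 0.21); the next 3 lower UF regions lay on chromosome X near Mid1 (-0.85 to -0.78). The smallest adjusted p was 1.00 in IP and 0.557 in UF. In simulated counts of these libraries, 15 of 50 genes changed 1.5-fold and 37 of 50 changed 2-fold were recovered in IP, and 36 and 45 in UF. Of 50 regions changed 2-fold and 50 changed 4-fold, 0 and 20 were recovered in IP and 11 and 49 in UF. A split by odd and even replicate number, even over AMPH and saline, called 465 genes in IP. With a term for it the counts for AMPH in IP and UF stayed 0. Splits that followed total counts, with AMPH libraries 1, 3 and 4 and saline library 1 the shallowest, called more. They are uneven over AMPH and saline, and no term for them was fitted.

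At 24 h after 6 daily injections, the comparison asks whether repeated AMPH leaves a change. No gene passed in either fraction, 34 regions were lower after AMPH in UF and 11 in PV IP, and none was higher. Of the 34 UF regions, 30 lay outside genes in the first 50 kb of assembled sequence of chromosome 9, from 3.0 Mb on, such as 3,014,115 to 3,014,314 with 69.6 ± 11.3 CPM after AMPH and 249.9 ± 51.3 CPM after saline (SD, n = 4 each; log2 fold change -1.85 ± 0.16, adjusted p = 1.4e-09). That stretch held 0.181 ± 0.0289% of UF counts after AMPH and 0.579 ± 0.117% after saline (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allow, 0.2 adjusted over 7 comparisons). In IP it held 0.373 ± 0.125% and 0.711 ± 0.518% (exact permutation p = 0.229), and in UF at 60 min 0.490 ± 0.0799% and 0.542 ± 0.251% (exact permutation p = 0.8).

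**Figure D5:**
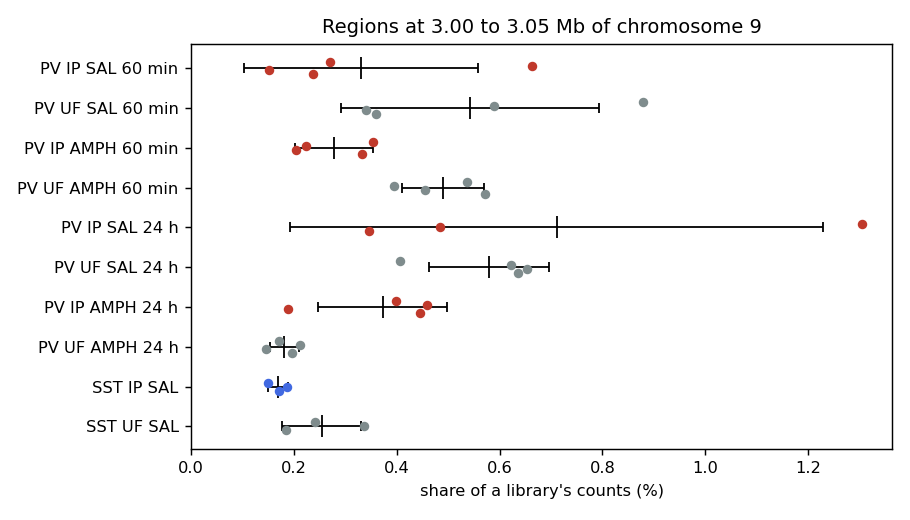
Share of each library's counts (percent) in regions of the first 50 kb of assembled sequence of chromosome 9, by group (points, libraries; bars, mean and SD). In UF at 24 h the mean was 0.181% after AMPH and 0.579% after saline, with every AMPH library below every saline library.

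The other 4 UF regions were chosen for naming after their values were seen. They lay in Chl1, a neural cell adhesion gene (chromosome 6, 103,649,218 to 103,649,417; 329 ± 64.9 against 787 ± 258 CPM; -1.34 ± 0.14, adjusted p = 3.8e-08), in Hspa2 (13.7 ± 2.17 against 40.1 ± 23.1 CPM; -1.51 ± 0.28, adjusted p = 0.00728), in Ano2 (7.81 ± 7.27 against 46.0 ± 52.8 CPM; -2.89 ± 0.40) and on chromosome X near Pak3 (100.4 ± 21.2 against 316 ± 102 CPM; -1.73 ± 0.20). In 32 of the 34 regions every AMPH library lay below every saline library. Chance gives that order in 1 of 70 regions not chosen by their call, a share that does not hold for these, as they were called lower and 30 share 1 stretch. In none of the 11 IP regions were the groups fully apart, 10 lay outside genes and 1 in Dop1b (chromosome 16, 93,789,167 to 93,789,366), with 31.9 ± 24.1 CPM (n = 4) against 55.8 ± 25.6 CPM (n = 3), -1.41 ± 0.26, adjusted p = 0.0236. With the Iso term the IP folds rest on the Iso2 libraries, since AMPH library Iso1-1 is the only Iso1 one. The CPM means include that library. In both fractions the called regions were among those of high counts. Their median logCPM was 5.67 in IP and 6.16 in UF, against 2.37 and 2.91 in regions not called. The cause of this was not tested.

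Gene lists did not separate AMPH from saline at 24 h. The immediate early list had medians of -0.07 in IP and 0.00 in UF, the late response list 0.00 and -0.05, the dopamine list 0.02 and 0.09 and the SPN list -0.03 and 0.09, with no member called. All 11 astrocyte genes were below 0 in IP (median -0.34, range -0.80 to -0.03), none called; camera called the list with the preset correlation (adjusted p = 9.4e-05), which did not hold (adjusted p = 0.808 with an estimated correlation). The oligodendrocyte median was 0.04 in IP and -0.21 in UF. Pvalb was 45.7 ± 3.83 CPM after AMPH (SD, n = 4) and 53.5 ± 10.7 CPM after saline (n = 3) in IP.

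edgeR called 0 of 16,243 genes in IP (608 at an unadjusted p under 0.05; DESeq2 0) and 0 of 15,788 in UF (560; DESeq2 1), and the interaction gave 0 of 116,361 regions (5212; DESeq2 21). The 11 IP regions, of 90,202 tested, fell to 0 without the Iso term, without IP saline library Iso2-3 or without IP AMPH library Iso2-3, to 3 without IP saline library Iso2-2 and to 6 without IP AMPH library Iso2-1, and rose to 45 without IP saline library Iso2-1; DESeq2 called 5. The 34 UF regions, of 64,477 tested, were 69 without UF saline library Iso2-1, 52 without UF saline library Iso2-2 or UF AMPH library Iso2-1, 6 with all libraries in 1 fit and 3 without the chromosome 9 stretch and the mitochondrial-like regions. In IP and in UF the counts rose with no filter and with the replicate number as a block. In simulated counts, 39 of 50 genes changed 2-fold in IP and 43 of 50 in UF were recovered, but 4 of 50 regions changed 2-fold in each, and 33 of 50 (IP) and 43 of 50 (UF) regions changed 4-fold.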

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

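The tests of depth, isolation number and background for the chromosome 9 stretch, and the test of unbound nuclei for the SPN genes, were chosen after those results were seen; the permuted groupings of the table differences and the set test of the SPN genes were chosen before.

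A single library stood apart from the other 3 of its group in 3 of 49 such checks, where chance gives about 1 in 20. AMPH IP library 2 at 60 min had a fraction score of 0.123, against -0.296 to -0.242 in the others. It stood apart only within its group: saline IP libraries 2 and 4 had 0.127 and 0.183, and 1 and 5 had -0.258 and -0.223. Saline UF library Iso2-2 at 24 h had a chromosome 9 share of 0.405%, against 0.622 to 0.654%. AMPH IP library Iso2-3 at 24 h had a mitochondrial-like share of 1.06%, against 0.776 to 0.797%.

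The IP over UF fold change differed between the PV and SST tables at 3653 genes, and 1 of 30 permuted groupings of the fraction labels within each table, the real one, gave as many (highest other 904). It differed between the 60 min and 24 h PV tables at 78 genes, and 2 of 30 groupings gave as many (highest other 1009). Permuting the fraction labels also moves the fraction effect of a table into the spread between libraries, so these groupings do not decide whether chance gave either difference.

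SPN genes were lower in PV IP than in UF at 60 min and not in SST IP. Chance among genes is argued against by the set test of the difference between the tables (adjusted p = 0.00754 with an estimated correlation, median -0.86 on the log2 scale). A larger share of unbound nuclei in the SST IP libraries stays open. Of the 22 genes 8 were called higher in SST IP than in UF and 2 lower (median 0.08), where 4877 of all 16,883 genes were called higher and 4960 lower. CPM are relative, so with fewer counts from oligodendrocytes and microglia, genes of carried-over nuclei can pass their UF level. The mean log2 CPM of the SPN list also differed between the UF libraries. It was 6.08 to 6.25 in saline PV UF at 60 min and 5.54 to 5.67 in SST UF. In IP it was 5.39 to 5.59 for PV and 5.72 to 5.78 for SST. The levels are summed over different regions in each table, so they do not show which fraction holds the difference. Also open are a difference between the table preparations, since the PV and SST libraries are separate sets, and a biological one: SST+ nuclei may share accessible regions of these genes with SPNs, which was not tested.

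The first 50 kb of assembled sequence of chromosome 9 held less of the UF counts after repeated AMPH than after saline at 24 h. The isolation number is argued against: 3 of 4 AMPH and 2 of 4 saline libraries are Iso1, so it would need a share 1.59 percentage points lower in Iso1 than in Iso2, and the share in Iso1 was higher by 0.131 in saline and 0.0133 in AMPH. More background reads in the saline libraries stay open. In the weakest 25% of regions the highest saline share was 1.08 times the AMPH mean, while the lowest saline share of the stretch was 2.23 times it. These regions were chosen on the libraries and reads outside regions are not in the counts, so they cannot decide on background. Lower depth of the saline libraries also stays open. The 2 shallower saline libraries, which are the Iso1 ones, had 0.131 percentage points more than the 2 deeper ones, where the treatments differ by 0.398, and the shallowest saline IP library had 1.30%, the highest share in IP. Against depth alone, the 2 deeper saline libraries (3.4 and 3.5 M) had 0.622 and 0.405%, and the shallowest AMPH library (2.2 M) had 0.212%. In saline mice 37 regions of the stretch were called lower in SST IP than in UF (share 0.169 against 0.254%, exact permutation p = 0.2), and none of 44 at 60 min and 42 at 24 h was called between PV IP and UF. An effect of AMPH, a difference in the order of preparation and reads from repeats elsewhere in the genome, for which no sequence was used here, stay open, so AMPH is no more than a candidate explanation.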

How the results depend on the processing

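Regions within 1 kb of gene ends, leaving out the chromosome 9 stretch, the 2 shallowest libraries or those of lowest fraction score, the fraction score as covariate, the odd or even term and every alternative of the table differences were chosen after the data were seen; the others were planned. Where a value moved, the cause was not tested unless stated. Depth and the spread between libraries limit together what can be seen, and no test set them apart. In simulated counts with both, 10 of 50 regions changed 2-fold were recovered for PV at 60 min, 23 for SST and 0 for PV at 24 h. Saline IP libraries had mean totals of 7.9, 7.9 and 3.5 M. Only 50 regions at each of 4 folds were changed in each simulation, while the real fits called 44.8, 46.8 and 19.1% of regions. Adjustment is stricter where fewer regions change, so these recoveries can understate what the fits of IP against UF see.

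With each library left out in turn, calls ranged as follows. PV at 60 min: 74,689 to 90,380 regions, 3153 to 4657 genes, 8 to 11 gene lists. SST: 69,519 to 83,608 regions, 7914 to 11,519 genes, 5 to 6 lists. PV at 24 h: 5812 to 14,401 regions, 1297 to 2782 genes, 6 to 7 lists. AMPH at 60 min: 0 to 3 lists in IP and 0 to 2 in UF. AMPH at 24 h: 0 to 45 regions, 0 to 4 genes and 1 to 4 lists in IP, 30 to 69 regions and 0 to 2 genes in UF, and 0 to 2 regions for the interaction. Between tables: 2263 to 4659 genes for PV against SST and 2 to 709 for 60 min against 24 h.

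Each named gene and region was followed through the alternatives that apply to it. Of the named genes 51 of 75 for PV at 60 min, 75 of 98 for SST and 20 of 51 for PV at 24 h kept direction and call in all of them, with 51, 44 and 113 values weaker. All named regions of the 3 comparisons of IP with UF and of AMPH IP at 60 min did so, as did 8 of 10 for AMPH UF at 60 min, 5 of 10 for AMPH IP and 4 of 15 for AMPH UF at 24 h. Planned and not run were regions within 1 kb of a transcription start and the AP-1 motif, and Iso2 libraries alone were run only for PV IP against UF and AMPH IP at 24 h (17,629 and 12 regions).

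With an estimated correlation no list was called in any comparison within a table: 0 in place of 10 (PV at 60 min), 6 (SST), 6 (PV at 24 h), 1 (AMPH IP at 60 min) and 1 (AMPH IP at 24 h). Regions within 1 kb of gene ends gave 2226 genes for PV at 60 min, 1169 at 24 h and 0 lists for AMPH IP at 60 min, from fewer regions, and these called values changed sign: at 60 min Crhr1 -0.48, Pde10a 0.76, Adcy5 0.22, Pdgfrb -0.25 and, under the name Slc1a2 PV IP vs UF 60min saline, 0.00433, in SST Pde10a 0.48 and Mbp 0.78, and at 24 h Pde10a 0.83. DESeq2 gave 9185 regions for PV at 24 h, 2 for AMPH UF at 60 min, 5 for AMPH IP at 24 h, 21 for the 24 h interaction, 1 gene for AMPH UF at 24 h and 326 genes for 60 min against 24 h. All libraries in 1 fit gave 23,013 regions for PV at 24 h, and 0 (IP) and 6 (UF) for AMPH at 24 h. No filter gave 36, 78 and 1 regions for AMPH at 24 h in IP, UF and the interaction. Without the Iso term AMPH IP at 24 h gave 0 regions; without the chromosome 9 stretch and mitochondrial-like regions UF gave 3; with the fraction score as covariate UF gave 1 gene; without the libraries of lowest fraction score AMPH IP at 60 min gave 0 lists. A minimum absolute log2 fold change of 1 left 8736 regions lower in both PV and SST.

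The labels do not say that equal replicate numbers share a mouse, and the correlations of same-numbered libraries did not all pass the preset 0.1 in any comparison. They were 0.0880 to 0.299 against -0.186 to 0.0828 for others in PV at 60 min, 0.0538 to 0.115 against -0.100 to -0.0111 in SST, and no more than 0.0487 in the 24 h comparisons. Between AMPH and saline at 60 min, libraries of other numbers reached 0.451 in IP and 0.380 in UF, above the highest of equal numbers (0.201 and 0.170). Every library correlated best with its own number in PV at 60 min and in SST, and not in the other comparisons with 3 pairs. UF is the supernatant of the IP step, so IP and UF libraries of equal number may come from 1 mouse. The main tests, with the interactions, treated them as independent. With the replicate block the counts were 88,980 regions and 6611 genes for PV at 60 min, 87,430 and 9764 for SST, 11,403 and 1712 for PV at 24 h, 8 regions and 2 genes for AMPH UF at 60 min, 33 regions for AMPH IP, 51 regions, 1 gene and 1 list for AMPH UF and 4 regions for the interaction at 24 h.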

Other observations

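All tests of the endothelial pattern, the term for odd or even numbers and the splits for the genes of the interactions were chosen after the results were seen; the other splits of the libraries were planned.

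Some immediate early and late response genes, compared between AMPH and saline above, were called between the fractions in saline mice, though neither list passed camera (adjusted p = 0.127 or more with the preset correlation). Fry passed the late response list in PV at 60 min (adjusted p = 0.0486) and 24 h (0.0086) and not in SST (0.362). It passed the immediate early list in none (fry adjusted p = 0.0717 or more). In PV IP at 60 min 2 of 25 immediate early genes were higher than in UF and 6 lower (2 and 7 adjusted over the list alone; median -0.03; camera adjusted p = 0.489). Egr3 and Egr4, transcription factors induced by activity, fell by 1.05 ± 0.15 and 1.10 ± 0.17 on the log2 scale (n = 4 against 4), and Atf3, a stress-induced factor, rose by 1.01 ± 0.19. At 24 h Egr3 (-1.43 ± 0.26), Egr4 (-1.68 ± 0.24) and Arc (-1.14 ± 0.19) were lower in PV IP and Atf3 (1.25 ± 0.26) and Nr4a2 (1.28 ± 0.28) higher (4 of 25 higher and 6 lower; 9 and 6 adjusted over the list alone; median 0.14). In SST IP 4 were higher and 11 lower (median -0.21), with Fosb (-1.01 ± 0.12) and Dusp1 (-0.82 ± 0.14) among the lower. Of the 15 late response genes, Bdnf (-0.91 ± 0.23) and Nrn1 (-0.95 ± 0.26) fell in PV IP at 60 min (median -0.17) and Vgf (-0.56 ± 0.17) at 24 h (median -0.34), while in SST IP 6 rose, with Scg2 at 0.80 ± 0.13, and 6 fell (median -0.04). Adjusted over the list alone, the counts for SST IP and for the late response list were equal.

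Some receptor genes were called, and their list did not pass camera in any comparison of IP with UF. Fry passed it in SST (adjusted p = 0.0080), where most lists passed, housekeeping among them (2.1e-04), and not in PV at 60 min (0.719) or 24 h (0.191). Of 16 glutamate and GABA receptor genes, 10 rose and 2 fell in SST IP, also when adjusted over the list alone (median 0.36; camera adjusted p = 0.0977), with the GABA-A subunit Gabrd among the lower (-0.72 ± 0.13). In PV IP at 60 min Gabbr2, a GABA-B receptor subunit (0.71 ± 0.13), and Grin2b (0.42 ± 0.14) rose (1 adjusted over the list alone; median 0.07), and at 24 h 1 rose and 3 fell (median -0.25). Of 5 genes of GABA synthesis and release, none rose in PV IP, 1 fell at 60 min (1 adjusted over the list alone; median -0.15) and 1 at 24 h (2 adjusted over the list alone; median -0.35). Gad1, which makes GABA, did not pass at 60 min (0.30 ± 0.14) or at 24 h (0.21 ± 0.23). Of 12 housekeeping genes 2 fell in PV IP at 60 min (median -0.28), 1 fell at 24 h (0 adjusted over the list alone; median -0.25), and in SST IP 5 fell and 1 rose (median -0.21). The called regions also lay in different places: of regions higher in PV IP at 60 min 9.25% lay within 2 kb of a gene end, of the lower ones 7.71% and of those not called 25.4%, for PV at 24 h 22.0%, 10.9% and 34.4%, and for SST 10.9%, 22.0% and 20.8%. Outside genes lay 35.1%, 43.4% and 30.1% of the PV regions at 60 min, 32.2%, 40.1% and 26.1% at 24 h and 50.2%, 35.0% and 36.4% of the SST regions, in the same order.

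Endothelial and mural genes were higher in PV IP than in UF at 60 min (5 of 10 genes called, median 0.85; fry adjusted p = 0.00993, but camera adjusted p = 0.141 with an estimated correlation). Loss of the main cell types from IP would raise the markers of the types that are not lost. The endothelial score rose above the microglia score by 1.82 ± 0.296 log2 units (SE, n = 4 each, exact permutation p = 0.0286, the smallest that 4 against 4 allow). Microglia genes themselves fell in PV IP (4 of 9 called, median -0.52). The score therefore holds their loss and does not decide on this explanation, which stays open. Vascular nuclei that stay with the beads in any Cre line remain open: the list was 0.81 higher in the PV than in the SST table, which did not pass (adjusted p = 0.469 with an estimated correlation). Cre activity or GFP in vascular or mural cells of the PV line is a candidate explanation that was not tested.

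Other splits of the same libraries were run for every count of called regions and genes. For PV IP against UF at 60 min 1 of 35 splits, the real one, gave as many regions (81,839, highest other 0) and genes (4232, highest other 0), and the same held at 24 h (14,735 regions, highest other 5818, and 2390 genes, highest other 966). This is the smallest share that 35 splits allow, so it does not exclude chance. The other splits also place a fraction effect in the spread between libraries, which lowers their counts. At 24 h the fit has an Iso term and all IP libraries are Iso2, so the splits are not alike. The 24 h split with 5818 calls is the split by fraction with UF library Iso1-1 moved to the IP libraries. For SST the 10 splits are too few for a share under 0.05: the real one gave 83,231 regions and 9837 genes and the highest other 0 of both. For the 34 UF regions lower after AMPH at 24 h 1 of 35 splits, the real one, gave as many (highest other 17), the smallest share that 4 against 4 allow. Chance is not excluded by this, since 30 of them lie in the chromosome 9 stretch, which is near to a single feature and whose share had a permutation p of 0.2 adjusted over 7 comparisons. For the 11 IP regions chance is not excluded either (7 of 35 splits, highest other 35). With the Iso term AMPH library Iso1-1 drops out of the fold, so some splits repeat others. The split that joins this library with the saline libraries is the real one again, with the same 11 regions.

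Where the real count was 0, every split gives as many whatever the data, so the shares say nothing about chance: 35 of 35 for regions and for genes at 60 min in IP and UF and for genes at 24 h in IP and UF, and 24 of 24 drawn for the regions and the genes of each interaction. The highest others were 0 regions and 1056 genes in IP and 3641 regions and 2093 genes in UF at 60 min, 3 and 36 genes in IP and UF at 24 h, and 1639 regions and 2464 genes at 60 min and 5 regions and 1 gene at 24 h for the interactions. For the genes of the interactions edgeR gave 76 at 60 min and 658 at 24 h at an unadjusted p under 0.05, and DESeq2 was not run. The splits with 1056 genes in IP and 3641 regions in UF join the same numbers, AMPH libraries 1, 3 and 4 with saline library 1. In each fraction these are the libraries of lowest total counts. They had up to 5.22 M in IP and 7.23 M in UF, and the others at least 7.56 M and 9.27 M. The split by odd and even numbers called 465 genes in IP. The interaction split with 2464 genes sets the odd IP numbers against the even ones. These point to a structure of the 60 min samples other than the treatment. Odd and even numbers are spread evenly over AMPH and saline, and with a term for them edgeR called 0 regions and 0 genes for AMPH in IP and in UF. That term does not model the grouping by total counts, which is uneven over AMPH and saline. Whether that grouping hid an AMPH effect was not tested.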
